A study of Mus musculus with 29 samples.

How the data were processed

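Poly-A RNA from the prostate tissue or tumours of 29 mice was sequenced, and the series holds 1 processed table with 23284 genes and 1 column per mouse. The values were deposited as log2 numbers, normalized for library size by the authors, and ran from 0.41 to 21.9. The submitters' processing notes name the mouse build mm9 and the tools bcl2fastq 1.8.4, TopHat, Cufflinks, DESeq and DESeq2 without role or order, and do not say how reads were counted. The low end of the scale had the form of variance-stabilized values: 6127 genes lay below 4.5 in every library, around a floor of 2.32, with a mean of 2.5 and an SD of 0.47 between samples. Log2 differences against groups near that floor are compressed, so their sizes and order are approximate. After reversing the logarithm, 100% of the values between 3000 and 6000 reads in each library fell on whole multiples of 1 step per library (within 0.03 of a whole number), and 5.6% to 7.6% did between 100 and 2000, where 6% is chance. These steps gave the size factor and the estimated depth of each library, 8.54 to 24.79 M reads, but not counts, so the precision of each value was taken from the spread between mice. No column was left without a group (0 not mapped), and 25 gene names had been turned into dates by a spreadsheet and were kept as they stand. No coordinates are given, since the annotation at hand (GRCm38) is not the authors' build and only named a gene's neighbours.

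Groups were taken from the labels: N, intact NP, castrated NP with vehicle or abiraterone, intact NPp53, and castrated NPp53 with vehicle, vehicle labelled outlier, abiraterone, or abiraterone labelled exp. The labels link no mice across groups for pairing and give no batch or date. The genes to test, the comparisons, the gene lists and the alternatives were fixed before the data were examined. A gene was tested if at least 10 normalized reads (a log2 value of 4.22) were reached in at least 3 samples, which left 16634 genes and excluded 6650. limma 3.58.1 (R 4.3.3) was fitted to the log2 values as they stand, with an intensity trend, a mean for each of the 9 groups and 1 shared estimate of spread (20 residual degrees of freedom). The NPp53 abiraterone comparison pooled exp and outlier libraries with their treatment (8 against 5, 11 residual degrees of freedom), since those labels can have followed from the outcome, and the abiraterone difference between genotypes used the 20 castrated libraries in 4 groups. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested, and an adjusted p under 0.05 was called. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

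The genes named in the text were the 8 largest rises and 8 largest falls per comparison among called genes whose groups did not overlap, whose mean in the higher group reached the median of tested genes, and whose symbol was not a clone or predicted name. For the interactions and for exp against outlier the 4 largest each way were taken. Every named gene therefore moved in its direction in all libraries of the groups compared, apart from the interactions. Members of the gene lists were also named, as the examples with small p. The 29 lists were targeted genes, androgen response, prostate secretory, luminal epithelium, basal epithelium, castration-tolerant luminal progenitor, neuroendocrine, mesenchymal, fibroblast, smooth muscle, skeletal muscle, endothelium, macrophage, neutrophil, T cell, B and plasma cell, erythroid, adipocyte, Schwann cell, seminal vesicle, urothelium, proliferation, p53 targets, steroidogenesis, glucocorticoid response, interferon response, senescence and secretory factors, cholesterol synthesis and epidermal genes. Erythroid genes had 1 tested member and were not tested as a list. The other 28 lists were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Of 336 list tests 122 were called with the preset correlation and 1 with the estimated one, the prostate secretory list after castration in NP. Median, mean and test direction of a list differed in sign in 33 of the 336, of which 0 were called.

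The alternatives fixed beforehand were no filter, a minimum of 50 normalized reads (14618 genes), TMM rescaling (own code, factors of at most 0.05 log2), quantile normalization, limma array quality weights, a fit of only the groups compared, leaving out each library, other uses of the exp and outlier libraries, and the estimated correlation. The seminal vesicle level as a covariate and a fit without the exp and outlier libraries were added after the data were examined. The test was checked on simulated data, where known shifts were added to 100 genes of each of 2 sizes in libraries of the same group sizes. It recovered 27% to 56% of shifts of 1 log2 unit and 64% to 86% of shifts of 2, with 0 to 11 false calls per comparison among 98 to 152 calls.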

Results

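Poly-A RNA of prostate tissue or tumours was sequenced from 29 mice, 1 library each. All mice carried a tamoxifen-inducible Cre recombinase in Nkx3-1, a homeobox gene of prostate epithelium. They received tamoxifen at 100 mg/kg per day for 4 days at 3 months of age. N mice carried the Cre allele alone (n = 3, 9 months). NP mice also carried floxed alleles of Pten, a phosphatase that restrains PI3K signalling. NPp53 mice carried floxed Pten and floxed Trp53, which encodes the p53 tumour suppressor. Vehicle-treated intact tumours came from NP (n = 3, 14 months) and NPp53 mice (n = 3, 12 months). NP mice castrated at 13 months were sampled at 16 months after vehicle (n = 4) or abiraterone (n = 3). NPp53 mice castrated at 10 months were sampled at 13 months after vehicle (n = 5) or abiraterone (n = 8). Abiraterone, an inhibitor of androgen synthesis, was given at 200 mg/kg per day on 5 days per week for 4 weeks. The labels set apart 2 of the NPp53 vehicle libraries as outlier and 3 of the NPp53 abiraterone libraries as exp, without defining either word. That leaves 3 other vehicle and 5 other abiraterone libraries. Castrated mice carried a RosaEYFP reporter allele unnamed in labels of intact mice, and were older than intact mice of their genotype. Castration, reporter, age and label prefix (CMZ, NC) changed together. The series title names transdifferentiation and treatment resistance in castration-resistant disease.

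Estimated depth ran from 8.54 M reads (exp replicate 3) to 24.79 M reads (NPp53 intact replicate 2), with a median of 20 M. Mean depth was 21.06 ± 2.11 M reads in N and 22.5 ± 1.94 in intact NP (SD). Other group means ran from 15.32 ± 6.09 (exp) to 23.33 ± 1.37 (intact NPp53). The 10 most abundant genes took 26.9% to 34.9% of the reads in N, 7% to 14.4% in intact NP and at most 8.3% elsewhere. Over the 16634 genes tested, the first principal component held 30.3% of the variance. It set the exp libraries (-160.5, -76.5 and -158.1) and the outlier libraries (-133.7 and -127.7) apart from the others (-13.8 to 45.9). The second component held 26% and set N (149.7 to 167.1) apart from the other libraries, which reached at most 50.7. Across genes, which are not independent replicates, Pearson's r between libraries of a group was 0.939 or higher in 7 groups. It was 0.907 to 0.913 between exp libraries and 0.817 between the outlier libraries. All differences given are log2 differences with the standard error of the fit, and all levels are log2 values with the SD.

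**Figure D1:**
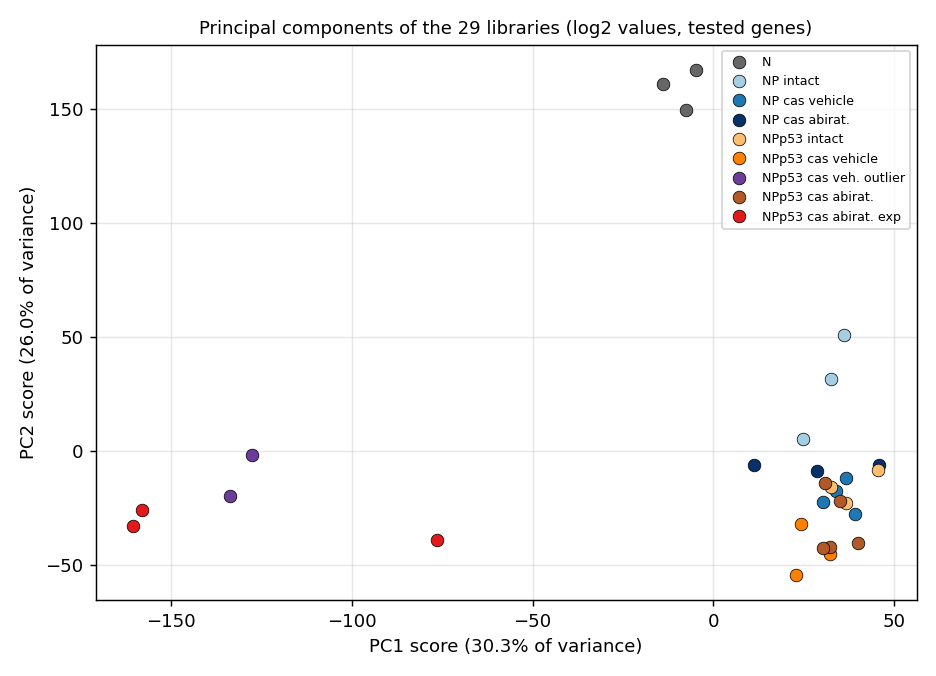
Scores of the 29 libraries on the first principal component (30.3% of the variance) and the second (26%), with 1 point per library, coloured by group. The exp and outlier libraries lie at -160.5 to -76.5 on the first component and the N libraries at 149.7 to 167.1 on the second.

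The 3 genes targeted by the crosses were examined first. Trp53 stood at 9.38 ± 0.05 in N (n = 3) and 10.04 ± 0.17 in intact NP (n = 3). In castrated NP it stood at 10.2 ± 0.11 with vehicle (n = 4) and 10.29 ± 0.2 with abiraterone (n = 3). NPp53 levels of Trp53 were 8.95 ± 0.06 in intact tumours (n = 3), 9.45 ± 0.17 in the other vehicle (n = 3) and 8.42 ± 0.05 in the outlier libraries (n = 2). They were 9.19 ± 0.32 in the other abiraterone (n = 5) and 8.97 ± 0.45 in the exp libraries (n = 3). Trp53 rose by 0.66 ± 0.19 from N to intact NP (adjusted p = 0.00764) and fell by 1.09 ± 0.19 from intact NP to intact NPp53 (adjusted p = 0.00495). Pten fell by 0.56 ± 0.13 from N (11.58 ± 0.26) to intact NP (11.01 ± 0.04, adjusted p = 0.00212) and had means of 11.09 to 11.38 in the other 7 groups. Nkx3-1 stood at 14.87 ± 0.76 in N and fell by 7.68 ± 0.87 in intact NP (adjusted p = 7.31e-07), where its libraries ran from 4.25 to 10.57. Its mean was 4.76 ± 0.55 in intact NPp53 and 2.45 to 3.84 in the castrated groups, near the floor of the file. Between N and intact NP the targeted list was not called (median -0.56, adjusted p = 0.302). From intact NP to intact NPp53 it fell (median -1.09, adjusted p = 0.0164, and adjusted p = 0.224 with an estimated correlation), with Trp53 as the only 1 of the 3 genes called.

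Intact NP tumours were compared with N prostates for the tissue after Pten loss. Age (14 and 9 months), vehicle (none named for N) and label prefix differed. Dmbt1, a mucin-like defence glycoprotein, rose by 13.07 ± 1.41 (adjusted p = 4.44e-07). The antimicrobial lectins Reg3b (11.87 ± 1.42, adjusted p = 1.43e-06) and Reg3g (10.67 ± 1.18, adjusted p = 5.88e-07) rose with it. So did the neutrophil attractant Cxcl5 (8.81 ± 1.12, adjusted p = 3.08e-06), lactoferrin Ltf (8.44 ± 1.24, adjusted p = 1.71e-05) and the gel-forming mucin Muc5b (8.14 ± 1.72, adjusted p = 0.00076). The transcription factor Onecut2 (8.19 ± 1.25, adjusted p = 2.7e-05) and the membrane protease Tmprss4 (8.11 ± 0.92, adjusted p = 7.62e-07) completed the 8 named rises. The secreted prostate transglutaminase Tgm4 (-8.39 ± 0.94, adjusted p = 6.6e-07), probasin Pbsn (-7.77 ± 1.5, adjusted p = 0.000333) and Nkx3-1 had the largest falls. The complement protease gene C1rb (-7.66 ± 1.17, adjusted p = 2.6e-05), the lipase-related Pnliprp1 (-7.64 ± 1.09, adjusted p = 1.21e-05) and the metallothionein Mt3 (-6.46 ± 0.83, adjusted p = 3.28e-06) fell too. Glb1l3 (-5.85 ± 1.12, adjusted p = 0.000298) and gasdermin Gsdma (-5.83 ± 1.32, adjusted p = 0.00143) completed the falls. In N, Dmbt1 (2.14 ± 0.65), Cxcl5 (2.47 ± 0.7), Reg3b (2.87 ± 0.27) and Onecut2 (2.89 ± 0.79) lay at the floor, where the scale compresses differences. Reg3b and Reg3g are close paralogs whose reads can be shared.

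In all, limma called 6261 of 16634 genes between intact NP and N (3279 higher and 2982 lower, Benjamini-Hochberg adjusted, n = 3 and 3). Of these, 3371 differed by over 2-fold. Among 9 castration-tolerant luminal progenitor markers 8 rose (9 adjusted over the list alone), such as Wfdc2 (7.5 ± 1.04) and Clu (4.46 ± 0.72). Among 23 proliferation genes 18 rose, such as Plk1 (3.82 ± 0.44) and Mki67 (2 ± 0.44). Of 16 interferon response genes 13 rose (14 adjusted over the list alone), such as Oas2 (4.76 ± 0.56) and Ifit1 (3.87 ± 0.66). Of 14 senescence and secretory factors 10 rose, such as the cell cycle inhibitor Cdkn2a (4.83 ± 0.3) and Tnf (3.45 ± 0.39). Macrophage genes rose in 9 of 10 cases, such as Cd14 (3.97 ± 0.38) and C1qb (2.57 ± 0.32). Neutrophil genes rose in 6 of 7 cases, such as S100a9 (4.9 ± 1). T cell genes rose in 7 of 9 cases, such as Cd3e (2.19 ± 0.54). Of 10 basal markers 7 rose, such as Dsg3 (4.88 ± 0.97) and Krt17 (2.49 ± 0.58). Fibroblast genes rose in 6 of 10 cases (7 adjusted over the list alone), such as Col1a1 (3.19 ± 0.96). Of 8 smooth muscle genes 4 fell, such as Synpo2 (-2.57 ± 0.76) and Acta2 (-2.13 ± 0.79). Luminal progenitor (median 4.19, adjusted p = 0.000125), proliferation (median 1.31, adjusted p = 4.66e-06), interferon response (median 2.5, adjusted p = 4.66e-06), senescence and secretory (median 3.27, adjusted p = 2.63e-06), macrophage (median 1.98, adjusted p = 4.66e-06), neutrophil (median 4.23, adjusted p = 0.00173), T cell (median 1.91, adjusted p = 0.0116), basal (median 2.14, adjusted p = 0.0467) and fibroblast (median 2.09, adjusted p = 0.0192) genes were higher as lists, with adjusted p = 0.32 or higher with an estimated correlation. Smooth muscle (median -2.35, adjusted p = 0.0332) genes were lower as a list, with adjusted p = 0.735 with an estimated correlation.

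The other 18 lists were not called between intact NP and N, with list adjusted p of 0.0556 to 0.961. Among 27 androgen response genes 5 rose and 9 fell (median -0.11, adjusted p = 0.346). Pmepa1 (3.96 ± 0.42) and the androgen receptor gene Ar (1.1 ± 0.4) were higher and the glycine methyltransferase Gnmt (-2.81 ± 0.22) lower. Among 12 prostate secretory genes 4 rose, such as 5430419D17Rik (8.1 ± 1.12) and Sbp (7.34 ± 1.44), and 3 fell (median -0.43, adjusted p = 0.852). Of 16 mesenchymal genes 7 rose, such as Mmp2 (3.35 ± 0.84) (median 1.15, adjusted p = 0.0556). Of 20 p53 targets 5 rose, such as Pmaip1 (4.64 ± 0.44), and 3 fell, such as Gdf15 (-3.06 ± 0.53) (median 0.2, adjusted p = 0.586). Of 12 luminal markers 1 fell, Dpp4 (-1.1 ± 0.39). Of 27 neuroendocrine genes 1 rose, Sox2 (2.89 ± 0.9). Epidermal genes rose in 2 of 11 cases, such as Krt6a (4.34 ± 0.91). All 16 named genes were called under every alternative run, and weighting libraries by quality raised the count to 11596. After quantile normalization 2682 genes were higher and 3718 lower, so the excess of rises turned with the scaling.

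Intact NPp53 tumours were compared with intact NP tumours for the addition of p53 loss, at 12 and 14 months. Interferon-induced genes were prominent among the rises, with Ifit3 (3.2 ± 0.73, adjusted p = 0.0271), Isg15 (2.94 ± 0.69, adjusted p = 0.0302) and Xaf1 (2.88 ± 0.42, adjusted p = 0.00101) higher in NPp53. The near-identical Apol9a (3.1 ± 0.72, adjusted p = 0.0286) and Apol9b (3.08 ± 0.71, adjusted p = 0.028), whose reads can be shared, were higher too. The lectin gene Clec2e (4.15 ± 0.79, adjusted p = 0.0104) and the collagenase gene Mmp13 (3.9 ± 0.99, adjusted p = 0.0429) had the largest rises. Gt(ROSA)26Sor, a noncoding RNA of the locus that carries reporter alleles, rose by 3.08 ± 0.29 (adjusted p = 4.58e-06). Its level was 6.11 ± 0.45 in intact NP and 9.19 ± 0.13 in intact NPp53. Falls were largest in the pseudogene Tmem181b-ps (-7.48 ± 1.42, adjusted p = 0.0105), Fam115e (-6.4 ± 0.89, adjusted p = 0.000763) and the MHC class II gene H2-Eb1 (-6 ± 1.5, adjusted p = 0.0385). Next came Glb1l3 (-5.83 ± 1.12, adjusted p = 0.0113), the protease inhibitor Spink11 (-4.62 ± 0.84, adjusted p = 0.00769) and the transglutaminase Tgm4 (-4.04 ± 0.94, adjusted p = 0.0286). The olfactory receptor Olfr1033 (-3.81 ± 0.78, adjusted p = 0.0154) and Fam55c (-2.69 ± 0.53, adjusted p = 0.0126) fell least of these 8 genes. Tmem181b-ps and H2-Eb1 also ran from 4.61 to 9.99 and from 7.57 to 12.55 within castrated NP with vehicle, so each varied widely between mice of a group as well.

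Of 16634 genes, limma called 311 between intact NPp53 and NP (171 higher, 140 lower, n = 3 and 3). Interferon response genes rose in 10 of 16 cases and in 16 adjusted over the list alone, such as Oasl1 (2.85 ± 0.5) and Irf7 (2.6 ± 0.59). As a list, interferon response genes had a median of 2.64 (adjusted p = 2.35e-19, and adjusted p = 0.224 with an estimated correlation). Of 14 senescence and secretory factors 2 rose, Cdkn2a (1.93 ± 0.3) and Mmp13. The 20 p53 targets had 0 called members (median -0.07, adjusted p = 0.564). Of 27 androgen response genes 1 fell, Gnmt (-1.1 ± 0.22) (median -0.02, adjusted p = 0.35). Smooth muscle genes had 0 called members over all genes and 8 of 8 lower adjusted over the list alone, such as Myh11 (-3.63 ± 1.34). Adipocyte genes had 4 of 6 lower adjusted over the list alone. Prostate secretory genes fell in 1 of 12 cases and in 3 adjusted over the list alone. Of 6 Schwann cell genes 1 fell, Plp1 (-1.97 ± 0.47). Smooth muscle (median -2.56, adjusted p = 3.46e-05), adipocyte (median -3.16, adjusted p = 0.00213), seminal vesicle (median -3.72, adjusted p = 0.00213), prostate secretory (median -1.72, adjusted p = 0.00637), Schwann cell (median -1.26, adjusted p = 0.00637), T cell (median -1.13, adjusted p = 0.00637), B and plasma cell (median -1.27, adjusted p = 0.00618), endothelium (median -0.68, adjusted p = 0.01) and skeletal muscle (median -1.34, adjusted p = 0.0164) genes were lower as lists, with adjusted p = 0.404 or higher with an estimated correlation. Senescence and secretory (median 0.91, adjusted p = 0.00213), basal (median 1.52, adjusted p = 0.00196), neutrophil (median 1.54, adjusted p = 0.00213), epidermal (median 0.85, adjusted p = 0.0163) and proliferation (median 0.43, adjusted p = 0.00101) genes were higher as lists, with adjusted p = 0.404 or higher with an estimated correlation. T cell, B and plasma cell, endothelium, skeletal muscle, basal, neutrophil, epidermal and proliferation genes had 0 called members over all genes. Some list medians depended on 1 library and were -0.67 for prostate secretory, 0.76 for neutrophil and 0.48 for senescence and secretory genes without NP intact replicate 2, -0.42 for endothelium genes without NP intact replicate 1, -0.74 for B and plasma cell genes without NP intact replicate 3, and -1.57 for seminal vesicle genes without NPp53 intact replicate 3. The count was 951 in a fit of these groups alone, 1358 without the exp and outlier libraries, 9825 with quality weights (4873 higher, 4952 lower) and 72 with the seminal vesicle level as covariate (35 higher, 37 lower). It was 142, 185 and 85 (28 higher, 57 lower) without NP intact replicate 1, 2 and 3, and 66, 65 (25 higher, 40 lower) and 114 without NPp53 intact replicate 1, 2 and 3, and Fam115e, Glb1l3, Gt(ROSA)26Sor, Tmem181b-ps and Xaf1 were the 5 of 16 named genes called without each single library. Clec2e, Fam115e, Fam55c, Spink11 and Tgm4 lost their call in the fit of these groups alone, and 8 of 16 with the covariate.

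Castrated NP tumours given vehicle were compared with intact NP tumours for the effect of castration. Transcripts of the seminal vesicle, an androgen-dependent gland beside the prostate, had the largest falls. Svs5 (-13.96 ± 1.69, adjusted p = 3.07e-05) and Svs2 (-13.15 ± 2.14, adjusted p = 0.00108) fell most, followed by Svs1 (-12.19 ± 2.49, adjusted p = 0.00715), Svs4 (-12 ± 2.27, adjusted p = 0.00417) and Svs6 (-10.88 ± 2.35, adjusted p = 0.00993). The related Svs3b (-10.63 ± 2.35, adjusted p = 0.0117), Svs3a (-10.62 ± 2.38, adjusted p = 0.0126) and Sva (-9.91 ± 2.38, adjusted p = 0.0196) fell as well. These genes are paralogs whose reads can be shared, and Svs1 (2.15 ± 0.12), Svs3b (2.18 ± 0.23) and Sva (2.1 ± 0.37) lay at the floor after castration. Rises were led by Gt(ROSA)26Sor (4.32 ± 0.27, adjusted p = 9.77e-10), whose intact NP level (6.11) lay far below N too (9.6). The water channel Aqp4 (3.82 ± 1.01, adjusted p = 0.0339), the carbonic anhydrase Car12 (3.74 ± 0.68, adjusted p = 0.00296) and the carnitine synthesis enzyme Bbox1 (3.38 ± 0.63, adjusted p = 0.00334) rose too. The bilirubin-conjugating enzyme Ugt1a1 (3.04 ± 0.79, adjusted p = 0.0301) rose with Gdpd3 (3.36 ± 0.92, adjusted p = 0.0408), Clec2e (3.34 ± 0.73, adjusted p = 0.0112) and Dapl1 (3.1 ± 0.67, adjusted p = 0.00991).

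Prostate secretory genes fell in 8 of 12 cases after castration in NP and in 11 adjusted over the list alone, such as 5430419D17Rik (-10.18 ± 1.05), Sbp (-8.38 ± 1.35) and Pbsn (-6.52 ± 1.41). Their list median was -5.91 (adjusted p = 5.11e-14, and adjusted p = 0.0107 with an estimated correlation). This was the 1 list call in the study that held with an estimated correlation. Of 27 androgen response genes 6 fell, including Gnmt (-1.86 ± 0.21), Eaf2 (-1.24 ± 0.2), Fkbp5 (-1.79 ± 0.3) and Nkx3-1 (-3.35 ± 0.81). The androgen response list had a median of -0.25 (adjusted p = 0.00554, and adjusted p = 0.255 with an estimated correlation). Seminal vesicle genes fell in 8 of 9 cases. As a list they had a median of -10.88 (adjusted p = 1.58e-12, and adjusted p = 0.11 with an estimated correlation). Smooth muscle genes fell in 1 of 8 cases, Actg2 (-3.32 ± 0.91), and in 8 adjusted over the list alone. The basal regulator Trp63 (1.52 ± 0.4) rose as 1 of 10 basal genes, with 4 adjusted over the list alone. Oas2 (1.87 ± 0.52) rose as 1 of 16 interferon response genes, with 6 adjusted over the list alone. Of 15 cholesterol synthesis genes 1 fell, Insig1 (-0.91 ± 0.24). Glucocorticoid response genes fell in 3 of 12 cases and rose in 1. Of 23 proliferation genes 1 fell, Plk1 (-2 ± 0.41). Luminal and neuroendocrine genes had 0 called members, and their lists were not called. Basal (median 1.38, adjusted p = 8.05e-05), interferon response (median 1.25, adjusted p = 9.48e-07), neutrophil (median 1.34, adjusted p = 0.0237) and epidermal (median 1.25, adjusted p = 0.0112) genes were higher as lists, with adjusted p = 0.301 or higher with an estimated correlation. Smooth muscle (median -2.58, adjusted p = 8.05e-05), cholesterol synthesis (median -0.37, adjusted p = 0.0111), glucocorticoid response (median -0.42, adjusted p = 0.0382) and fibroblast (median -0.99, adjusted p = 0.0111) genes were lower as lists, with adjusted p = 0.485 or higher with an estimated correlation. With 1 library left out, list medians were -0.61 for fibroblast genes without NP intact replicate 1, and 0.65 for neutrophil genes without NP intact replicate 2. In all 704 of 16634 genes were called by limma (252 higher, 452 lower, n = 4 and 3). A fit of these groups alone called 554 higher and 502 lower, without the excess of falls, and Clec2e lost its call there. The count was 2134 without the exp and outlier libraries, 8536 with quality weights and 72 with the seminal vesicle level as covariate, where 14 of 16 named genes lost their call and Svs1, Svs6, Svs3b, Svs3a and Sva changed sign. It was 185 and 246 without NP intact replicate 2 and 3 and 319, 325 and 453 without castrated vehicle replicate 1, 2 and 3, and Bbox1, Car12, Dapl1, Gt(ROSA)26Sor, Svs2, Svs4 and Svs5 were the 7 of 16 named genes called without each single library.

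**Figure D2:**
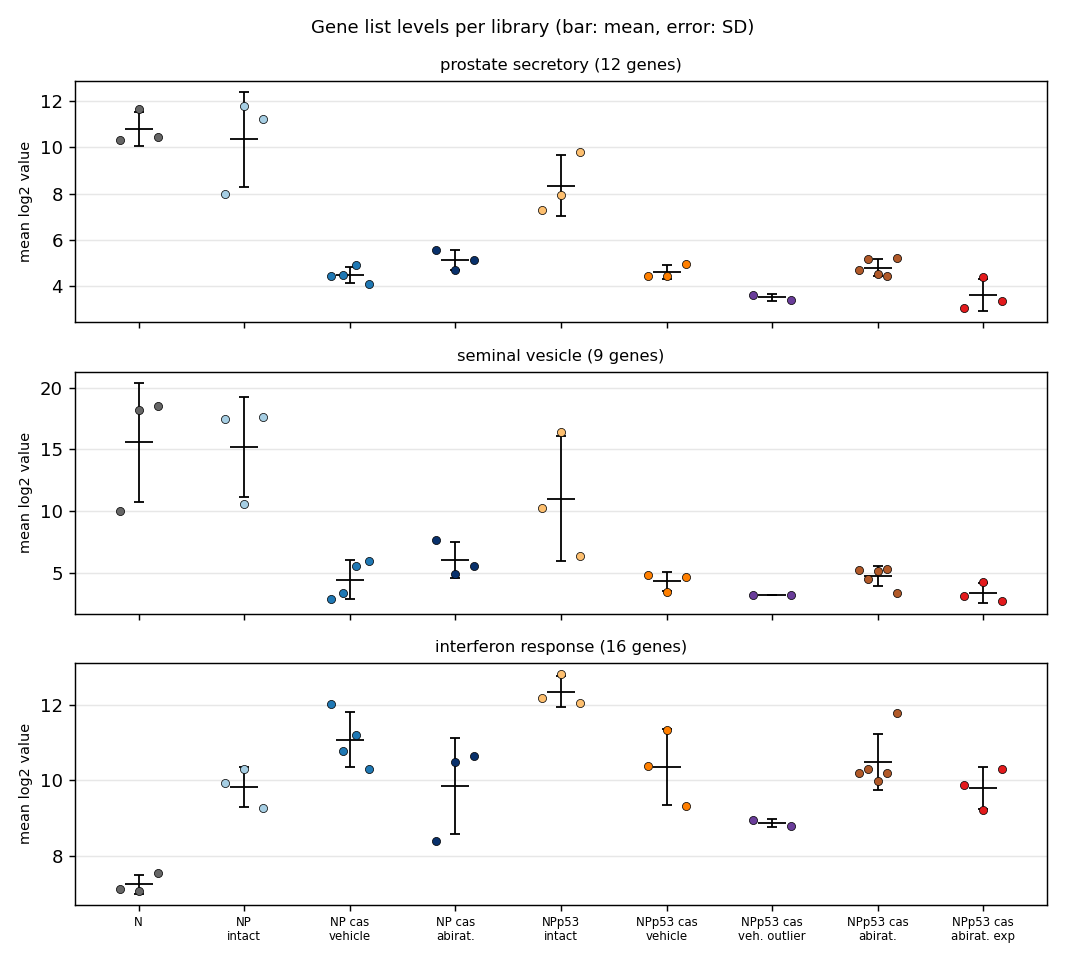
Mean log2 value of the 12 prostate secretory, 9 seminal vesicle and 16 interferon response genes per library, by group on the horizontal axis, with group means and SD as bars. The prostate secretory mean lies at 8 or above in intact NP and at most at 5.55 in the castrated libraries, and the seminal vesicle mean runs from 6.34 to 16.44 within intact NPp53.

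In NPp53 tumours, castration (13 months, vehicle, n = 3) was compared with intact tumours (12 months, n = 3). Secretory genes had the largest falls, with Svs5 (-10.74 ± 1.81, adjusted p = 0.00207), Svs4 (-9.56 ± 2.43, adjusted p = 0.0255) and Svs2 (-8.45 ± 2.29, adjusted p = 0.0361) of the seminal vesicle among them. The protease inhibitor Spink5 (-8.84 ± 0.94, adjusted p = 8.67e-06), the spermine-binding protein gene Sbp (-6.62 ± 1.44, adjusted p = 0.0101) and Sval1 (-6.35 ± 1.07, adjusted p = 0.00206) fell too. The salivary gland gene Smgc (-4.96 ± 1.05, adjusted p = 0.00827) and the apolipoprotein Apof (-4.81 ± 1.02, adjusted p = 0.00852) completed the falls. Svs5 (1.96 ± 0.41) and Sbp (2.53 ± 0.52) lay at the floor after castration. Rises were led by the peptidoglycan receptor Pglyrp4 (3.93 ± 0.88, adjusted p = 0.0121), the adenosine receptor Adora1 (3.06 ± 0.81, adjusted p = 0.0315) and the scavenger receptor Scara3 (2.27 ± 0.44, adjusted p = 0.00458). The lactate transporter Slc16a1 (2.1 ± 0.48, adjusted p = 0.0135) and the sialyltransferases St3gal1 (1.82 ± 0.48, adjusted p = 0.0309) and St6gal1 (1.82 ± 0.41, adjusted p = 0.0125) rose too. Rasgef1a (2.2 ± 0.63, adjusted p = 0.0472) and Phactr1 (2.04 ± 0.45, adjusted p = 0.0108) completed the 8 named rises.

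Prostate secretory genes fell in 5 of 12 cases in castrated NPp53 (6 adjusted over the list alone), such as 5430419D17Rik (-8.67 ± 1.12). The list had a median of -3.93 (adjusted p = 6.94e-06, and adjusted p = 0.284 with an estimated correlation). Of 27 androgen response genes 4 fell, Fkbp5 (-2.1 ± 0.32), Zbtb16 (-4.17 ± 0.77), Eaf2 (-1.16 ± 0.21) and Gnmt (-0.97 ± 0.22). The androgen response list had a median of -0.51 (adjusted p = 0.0245, and adjusted p = 0.295 with an estimated correlation). Seminal vesicle genes fell in 3 of 9 cases and in 7 adjusted over the list alone. As a list their median was -7.43 (adjusted p = 1.69e-05, and adjusted p = 0.352 with an estimated correlation). Interferon response genes fell in 5 of 16 cases and in 14 adjusted over the list alone, such as Ifit2 (-2.52 ± 0.49) and Ifit3 (-3.03 ± 0.73). Their list median was -2.04 (adjusted p = 1.06e-10, and adjusted p = 0.295 with an estimated correlation). Of 6 B and plasma cell genes 5 rose, such as Cd79b (2.74 ± 0.69) and Ms4a1 (3.01 ± 0.76). The list median was 2.83 (adjusted p = 8.37e-06, and adjusted p = 0.284 with an estimated correlation). Of 6 steroidogenesis genes 2 rose, Cyp11a1 (3.08 ± 0.89), the enzyme that opens steroid synthesis, and Srd5a1 (1.75 ± 0.51), a steroid reductase. As a list, steroidogenesis genes had a median of 1.08 (adjusted p = 0.0267, and adjusted p = 0.284 with an estimated correlation). Of 20 p53 targets 1 fell, Polk (-0.9 ± 0.22) (median 0.03, adjusted p = 0.53). Luminal and proliferation genes had 0 called members, and their lists were not called. Neutrophil (median 1.42, adjusted p = 0.0303), macrophage (median 0.4, adjusted p = 0.0303), T cell (median 0.94, adjusted p = 0.0336), endothelium (median 0.64, adjusted p = 0.0303), senescence and secretory (median 1.09, adjusted p = 0.0303) and cholesterol synthesis (median 0.32, adjusted p = 0.0267) genes were higher as lists, with adjusted p = 0.644 with an estimated correlation. The list median was -4.69 for seminal vesicle genes without NPp53 intact replicate 2. In all 773 of 16634 genes were called by limma (267 higher, 506 lower). The count was 4347 in a fit of these groups alone (2330 higher, 2017 lower), 2703 without the exp and outlier libraries, 1886 with all 5 vehicle libraries as 1 group and 6018 with quality weights (3032 higher, 2986 lower). Without NPp53 intact replicate 1, 2 and 3 it was 405, 241 and 267, and without vehicle replicate 1, 2 and 3 it was 398, 320 and 286, with Sbp, Scara3, Smgc, Spink5, Sval1 and Svs5 as the 6 of 16 named genes called in each. Sbp and Svs2 lost their call in the fit of these groups alone, and 4 of 16 with the covariate.

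The castration interaction tested the NPp53 change minus the NP change, and interferon-induced genes were prominent. Ifit3 (-4.39 ± 1, adjusted p = 0.0454) had a change of -3.03 in NPp53 and 1.36 in NP. Apol9a (-4.22 ± 0.98, adjusted p = 0.0471) and Apol9b (-4.47 ± 0.97, adjusted p = 0.0396) had changes of -2.59 and -2.79 in NPp53 and 1.63 and 1.67 in NP. The tyrosine phosphatase Acp1 (-5.53 ± 0.7, adjusted p = 0.000509) had changes of -2.85 in NPp53 and 2.68 in NP. Acp1 also ran from 6.45 to 8.57 within N and from 6.16 to 9.11 within castrated NP with abiraterone, like steps without a change of treatment. Positive differences were led by Fam115e (6.53 ± 1.22, adjusted p = 0.03), Spink11 (4.9 ± 1.15, adjusted p = 0.0471) and Fam55c (3.07 ± 0.73, adjusted p = 0.0471) and the transcription factor Gata2 (2.2 ± 0.49, adjusted p = 0.0451). Interferon response genes differed in 6 of 16 cases and in 16 adjusted over the list alone, such as Oas2 (-3.72 ± 0.77) and Ifit2 (-3.11 ± 0.67). Their list median was -3.41 (adjusted p = 4.14e-20, and adjusted p = 0.29 with an estimated correlation). Their mean level was 12.35 ± 0.4 in intact and 10.34 ± 1.01 in castrated NPp53, and 9.83 ± 0.53 and 11.07 ± 0.73 in NP (SD). Of 15 cholesterol synthesis genes 1 differed, Insig1 (1.48 ± 0.35). B and plasma cell genes had 0 called members over all genes and 5 of 6 adjusted over the list alone. Prostate secretory and androgen response genes had 0, the latter not called as a list (median 0.05, adjusted p = 0.866). Cholesterol synthesis (median 0.56, adjusted p = 9.63e-05), B and plasma cell (median 2.81, adjusted p = 0.000173), smooth muscle (median 3.2, adjusted p = 0.000173), prostate secretory (median 1.87, adjusted p = 0.0363), mesenchymal (median 1.17, adjusted p = 0.00926), fibroblast (median 1.56, adjusted p = 0.0129), endothelium (median 1.12, adjusted p = 0.00221), skeletal muscle (median 1.88, adjusted p = 0.00926), Schwann cell (median 1.65, adjusted p = 0.0363) and seminal vesicle (median 3.79, adjusted p = 0.0363) genes were positive as lists, with adjusted p = 0.457 or higher with an estimated correlation. Basal (median -1.1, adjusted p = 0.00926) genes were negative as a list, with adjusted p = 0.457 with an estimated correlation. Some list medians depended on 1 library and were 1.08 for prostate secretory genes without NP intact replicate 2, 0.74 for mesenchymal and 1 for fibroblast genes without NP intact replicate 1, 0.62 for skeletal muscle genes without NPp53 vehicle replicate 1, 1.23 for seminal vesicle genes without NPp53 intact replicate 3, and 0.36 for cholesterol synthesis genes without NPp53 vehicle replicate 2. The castration calls of the genotypes shared 112 lower genes where independence gives 13.7, and 30 higher genes where it gives 4, with 0 and 5 called in opposite directions (r = 0.33 across genes). In all 128 genes were called by limma (31 positive, 97 negative). The count was 1519 in a fit of the 4 groups alone, 824 without the exp and outlier libraries, 6356 with quality weights (3389 positive, 2967 negative), 52 with no filter, 77 after quantile normalization and 5 with the seminal vesicle covariate. Single left-out libraries gave 17, 47 and 20, of which 12 positive (NP intact replicates 1, 2 and 3), 14, 15 and 6 (castrated NP 1, 2 and 3), 23, 7, of which 4 positive, and 4 (NPp53 intact 1, 2 and 3) and 5, 76 and 8 (castrated NPp53 1, 2 and 3), and of the 8 named genes only Acp1 was called in each. With the covariate 6 of the 8 lost their call.

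Castrated NPp53 tumours were compared with castrated NP tumours, both after vehicle (n = 3 and 4, 13 and 16 months), for p53 loss under androgen deprivation. The cell cycle inhibitor gene Cdkn2a (1.95 ± 0.28, adjusted p = 0.0012) was the largest rise, followed by C1qtnf6 (1.93 ± 0.41, adjusted p = 0.0486) and Zc3h12d (1.61 ± 0.25, adjusted p = 0.00313). The secreted hormone Stc2 (1.33 ± 0.27, adjusted p = 0.0344), cathepsin Ctsa (0.74 ± 0.12, adjusted p = 0.00316) and Tnip1 (0.67 ± 0.13, adjusted p = 0.0344) were higher too. The actin regulator Cfl1 (0.62 ± 0.13, adjusted p = 0.0344) and the glycolytic enzyme Tpi1 (0.6 ± 0.13, adjusted p = 0.0494) had smaller rises. The phosphatase Acp1 (-3.03 ± 0.48, adjusted p = 0.00316) and the aldehyde oxidase Aox3 (-2.75 ± 0.59, adjusted p = 0.0486) had the largest falls. Ttc38 (-1.36 ± 0.29, adjusted p = 0.0486) and Metap1d (-1.23 ± 0.25, adjusted p = 0.0344) and the glycan enzyme Man2a1 (-1.17 ± 0.19, adjusted p = 0.00316) followed. Gprasp1 (-0.96 ± 0.17, adjusted p = 0.00898), the phosphatase Ptpn14 (-0.91 ± 0.16, adjusted p = 0.0105) and the chromatin protein Hmgb1 (-0.8 ± 0.12, adjusted p = 0.00313) fell least of the 8 named. Trp53 itself had a value of -0.75 ± 0.18 (adjusted p = 0.0651) and was called adjusted over the list alone. The targeted list had a median of -0.45 (adjusted p = 0.0307, and adjusted p = 0.144 with an estimated correlation).

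Proliferation genes had 0 of 23 called over all genes and 13 higher adjusted over the list alone, such as Aurkb (1.09 ± 0.31) and Foxm1 (0.89 ± 0.28). As a list, proliferation genes had a median of 0.86 (adjusted p = 5.63e-11, and adjusted p = 0.358 with an estimated correlation). Cholesterol synthesis had 0 of 15 and 7 higher adjusted over the list alone, such as Insig1 (0.98 ± 0.24) and Sqle (1.2 ± 0.3). Cholesterol synthesis genes had a list median of 0.43 (adjusted p = 1.4e-08, and adjusted p = 0.21 with an estimated correlation). Of 14 senescence and secretory factors 1 rose, Cdkn2a, and 4 adjusted over the list alone. The senescence and secretory list had a median of 1.7 (adjusted p = 1.49e-07, and adjusted p = 0.111 with an estimated correlation). The p53 targets had 0 of 20 called over all genes and 5 lower adjusted over the list alone, such as Ccng1 (-0.81 ± 0.18). As a list, p53 target genes had a median of -0.13 (adjusted p = 0.00203, and adjusted p = 0.111 with an estimated correlation). Neutrophil genes had 4 of 7 higher adjusted over the list alone. Neutrophil genes had a list median of 2.23 (adjusted p = 0.000525, and adjusted p = 0.488 with an estimated correlation). The interferon response list had a median of -0.85 (adjusted p = 0.00137, and adjusted p = 0.902 with an estimated correlation). B and plasma cell (median 1.54, adjusted p = 0.0142) and mesenchymal (median 0.59, adjusted p = 0.0379) genes were higher as lists, with adjusted p = 0.637 or higher with an estimated correlation. With 1 library left out, list medians were -0.2 for targeted genes without NPp53 vehicle replicate 2, 0.34 for mesenchymal genes without NPp53 vehicle replicate 1, and -0.29 for interferon response genes without NPp53 vehicle replicate 3. Androgen response, luminal and neuroendocrine genes had 0 called members, and their lists were not called. In all 42 of 16634 genes were called by limma (17 higher, 25 lower). The count was 1334 in a fit of these groups alone (768 higher, 566 lower), 858 without the exp and outlier libraries, 1035 with all 5 vehicle libraries (547 higher, 488 lower) and 3665 with quality weights (1986 higher, 1679 lower). Without castrated NP replicate 1, 2, 3 and 4 it was 16, 16, 27 and 35 (20 higher, 15 lower), and without castrated NPp53 replicate 1, 2 and 3 it was 22, 16 (8 higher, 8 lower) and 21, and Acp1, Cdkn2a, Ctsa, Hmgb1, Man2a1 and Zc3h12d were the 6 of 16 named genes called in each. Metap1d lost its call in the fit of these groups alone.

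Abiraterone was compared with vehicle in castrated mice for the response to a further block of androgen synthesis, and no gene passed the test in either genotype. In NP (n = 3 and 4), limma called 0 genes, with 641 at an unadjusted p under 0.05 where chance gives 832. In NPp53 (n = 8 and 5, exp and outlier libraries included) it called 0, with 178. Androgen response genes had 0 called members in NP (median -0.04, adjusted p = 0.917) and NPp53 (median 0, adjusted p = 0.778). Interferon response genes such as Ifit1 (-1.7 ± 0.62) were lower as a list in NP. As a list, interferon response genes had a median of -1.2 (adjusted p = 4.35e-14, and adjusted p = 0.534 with an estimated correlation). Among proliferation genes Mki67 had a value of -0.88 ± 0.41. Cholesterol synthesis genes such as Sqle (0.71 ± 0.3) and fibroblast genes were higher as lists. Cholesterol synthesis genes had a list median of 0.3 (adjusted p = 7.12e-06, and adjusted p = 0.534 with an estimated correlation). The fibroblast list had a median of 0.94 (adjusted p = 0.000143, and adjusted p = 0.626 with an estimated correlation). Mesenchymal (median 0.59, adjusted p = 0.00062) and smooth muscle (median 0.94, adjusted p = 0.00711) genes were higher as lists, with adjusted p = 0.626 with an estimated correlation. Proliferation (median -0.44, adjusted p = 1.59e-06), neutrophil (median -1.61, adjusted p = 1.59e-06), senescence and secretory (median -0.52, adjusted p = 0.0156), macrophage (median -0.15, adjusted p = 0.0345) and epidermal (median -0.71, adjusted p = 0.0345) genes were lower as lists, with adjusted p = 0.534 or higher with an estimated correlation. Where list medians depended on 1 library, they were 0.05 for mesenchymal, 0.13 for fibroblast and -0.5 for interferon response genes without castrated NP abiraterone replicate 1, 0.55 for smooth muscle genes without castrated NP vehicle replicate 1, 0 for macrophage genes without castrated NP abiraterone replicate 3, -0.28 for proliferation genes without castrated NP abiraterone replicate 2, and -0.14 for epidermal genes without castrated NP vehicle replicate 2. In NPp53, cholesterol synthesis genes such as Cyp51 (-0.83 ± 0.24) and Hmgcr (-0.65 ± 0.34) were lower as a list. Interferon response (median 0.55, adjusted p = 0.000638), macrophage (median 0.24, adjusted p = 0.0354) and neutrophil (median 0.66, adjusted p = 0.0354) genes were higher as lists, with adjusted p = 0.885 with an estimated correlation. Cholesterol synthesis (median -0.46, adjusted p = 1.3e-08), proliferation (median -0.54, adjusted p = 0.00906), neuroendocrine (median -0.53, adjusted p = 0.0354) and adipocyte (median -0.71, adjusted p = 0.0354) genes were lower as lists, with adjusted p = 0.665 or higher with an estimated correlation. Some list medians depended on 1 library and were 0.43 for neuroendocrine, 0.07 for macrophage, 0.01 for neutrophil and 0.06 for proliferation genes without outlier replicate 2, -0.33 for adipocyte genes without outlier replicate 1, and 0.29 for interferon response genes without NPp53 abiraterone replicate 5. Of these 7 NPp53 lists only cholesterol synthesis had the same sign with the exp and outlier libraries in or out. Without the outlier libraries the median was 0.28 for neuroendocrine, 0.65 for proliferation, -1 for neutrophil and -0.13 for interferon response genes. Without the exp libraries it was -0.12 for macrophage genes, and without both sets 0.23 for adipocyte genes. The abiraterone effects of the genotypes differed in 0 genes by limma (302 unadjusted) and in 7 lists. As a list, cholesterol synthesis genes had a median of -0.92 (adjusted p = 4.64e-12, and adjusted p = 0.177 with an estimated correlation). Interferon response genes had a list median of 1.71 (adjusted p = 2.97e-14, and adjusted p = 0.335 with an estimated correlation). Neutrophil (median 2.28, adjusted p = 5.09e-06), macrophage (median 0.36, adjusted p = 0.00812) and epidermal (median 1.15, adjusted p = 0.0408) genes were positive as lists, with adjusted p = 0.502 or higher with an estimated correlation. Neuroendocrine (median -0.81, adjusted p = 0.0153) and seminal vesicle (median -0.44, adjusted p = 0.0393) genes were negative as lists, with adjusted p = 0.502 or higher with an estimated correlation. With 1 library left out, list medians were 0.31 for neuroendocrine and 1.45 for neutrophil genes without outlier replicate 2, 0.23 for macrophage genes without castrated NP abiraterone replicate 3, -0.26 for seminal vesicle and 0.95 for interferon response genes without castrated NP abiraterone replicate 1, and 0.74 for epidermal genes without outlier replicate 1. Without the outlier libraries the median was 0.12 for neuroendocrine and 0.09 for epidermal genes, and without the exp libraries 0.01 for macrophage genes. On simulated data the test recovered 54% of changes of 1 log2 unit and 79% of 2 in NP, and 56% and 85% in NPp53. The median 95% interval, before adjustment, reached 0.55 to either side in NP and 0.68 in NPp53. A count of 0 therefore leaves changes of 1 and of 2 log2 units in single genes open, in NP, in NPp53 and in the difference between genotypes. With quality weights the NP count was 1031, and another split of the same libraries gave 1777.

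The 3 NPp53 abiraterone libraries labelled exp were compared with the 5 others, to describe the tumours the submitters had set apart. Mesenchymal genes were higher in them, and luminal and basal genes lower. The BMP antagonist Grem1 (8.06 ± 0.51, adjusted p = 7.11e-10), Fam5c (7.39 ± 0.92, adjusted p = 1.41e-06) and the IL-33 receptor Il1rl1 (6.64 ± 0.93, adjusted p = 5.22e-06) had the largest rises. The retinoic acid-binding Crabp1 (6.62 ± 0.86, adjusted p = 2.28e-06), stromelysin Mmp3 (6.6 ± 0.81, adjusted p = 1.13e-06) and the chromatin protein Hmga2 (6.41 ± 0.79, adjusted p = 1.26e-06) followed. The matrix proteins Cthrc1 (6.21 ± 0.73, adjusted p = 7.57e-07) and Edil3 (6.17 ± 0.73, adjusted p = 7.57e-07) rose as well. Surfactant Sftpd (-6.45 ± 1.08, adjusted p = 4.04e-05), the immunoglobulin transporter Pigr (-6.14 ± 0.88, adjusted p = 6.71e-06) and Ugt2b34 (-6.11 ± 0.83, adjusted p = 3.47e-06) fell. Gabrp (-6.08 ± 0.78, adjusted p = 1.87e-06), mucus-binding Fcgbp (-6.04 ± 0.96, adjusted p = 2.29e-05) and the androgen-regulated protease Tmprss2 (-5.93 ± 0.83, adjusted p = 5.49e-06) fell too. The gasdermins Gsdmc2 (-6.15 ± 0.98, adjusted p = 2.21e-05) and Gsdmc3 (-6.07 ± 0.96, adjusted p = 1.98e-05), whose reads can be shared, completed the falls.

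All 16 mesenchymal genes rose in the exp libraries, such as N-cadherin Cdh2 (4.33 ± 0.47), vimentin Vim (3.78 ± 0.44) and the repressor Zeb1 (2.92 ± 0.4). All 12 luminal genes fell, such as Cldn4 (-5.41 ± 0.78), Cdh1 (-4.15 ± 0.67) and Krt18 (-4.32 ± 0.76). Of 10 basal genes 9 fell, such as Trp63 (-3.5 ± 0.39) and Krt5 (-5.22 ± 0.72). All 9 castration-tolerant luminal progenitor markers fell, such as Clu (-4.94 ± 0.64) and Krt4 (-5.83 ± 0.76). All 23 proliferation genes rose, such as Foxm1 (3.17 ± 0.27) and E2f1 (3.15 ± 0.27). Fibroblast genes moved with the mesenchymal genes, 9 of 10 higher, such as Pdgfrb (3.45 ± 0.4) and Pdgfra (4.45 ± 0.64). Of 8 smooth muscle genes 1 fell (median -0.24, adjusted p = 0.865). Of 27 androgen response genes 12 fell, such as Slc45a3 (-4.56 ± 0.69) and Ar (-2.09 ± 0.36), and 3 rose (median -1.14, adjusted p = 0.0504). Among the latter was Fkbp5 (1.93 ± 0.28), also a glucocorticoid receptor target. Glucocorticoid response genes rose in 6 of 12 cases, such as the receptor gene Nr3c1 (0.61 ± 0.13) (median 0.67, adjusted p = 0.0982). Of 27 neuroendocrine genes 5 rose, such as Ncam1 (1.79 ± 0.35) and Eno2 (1.75 ± 0.38) (median 0.15, adjusted p = 0.352). Senescence and secretory factors rose in 7 of 14 cases, such as Cdkn2a (2.42 ± 0.27), and fell in 3, such as Tnf (-2.99 ± 0.35) (median 1.41, adjusted p = 0.0989). Epidermal genes fell in 7 of 11 cases. Mesenchymal (median 3.47, adjusted p = 2.53e-08), proliferation (median 2.74, adjusted p = 1.92e-14) and fibroblast (median 3.93, adjusted p = 0.000109) genes were higher as lists, with adjusted p = 0.417 or higher with an estimated correlation. Luminal (median -3.98, adjusted p = 6.59e-06), basal (median -4.14, adjusted p = 1.04e-05), luminal progenitor (median -5.18, adjusted p = 0.000149) and epidermal (median -1.96, adjusted p = 0.0195) genes were lower as lists, with adjusted p = 0.417 or higher with an estimated correlation. B and plasma cell genes fell in 5 of 6 cases and T cell genes in 4 of 9, with no list call. Schwann cell and urothelium genes each fell in 4 of 6 cases, and their lists were not called. Endothelium genes rose in 5 of 8 cases (median 1.4, adjusted p = 0.0504) and macrophage genes in 7 of 10 (median 0.97, adjusted p = 0.0903). In all 8425 of 16634 genes were called by limma (4120 higher, 4305 lower, n = 3 and 5). All 16 named genes were called under every alternative run, and quality weights gave 5560 calls. Falls exceeded rises in the fit, but quantile normalization gave 4218 higher and 3973 lower, and the fit without exp replicate 3 gave 3895 and 3771.

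**Figure D3:**
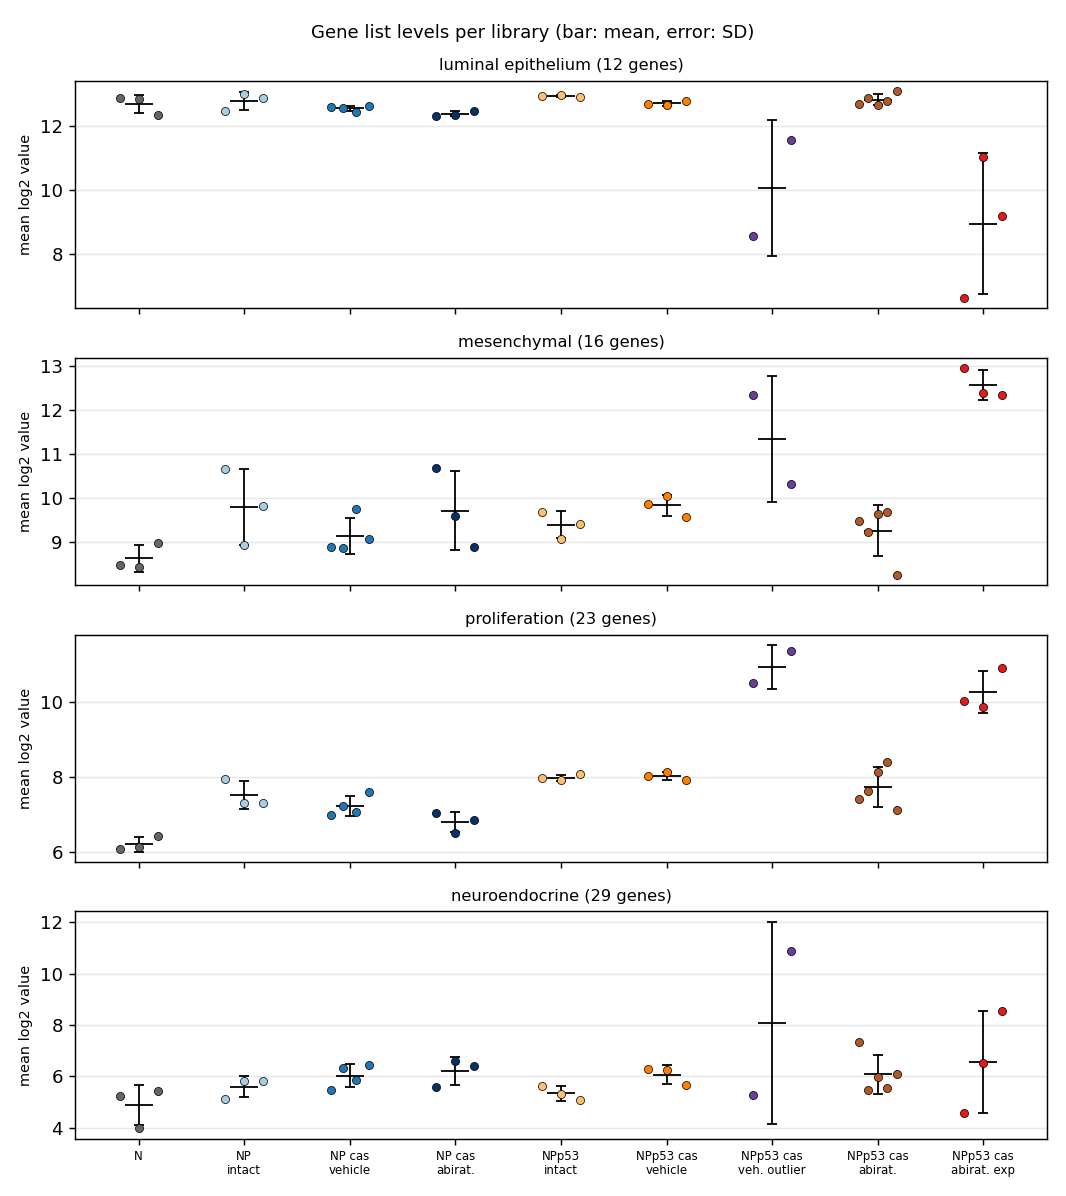
Mean log2 value of the 12 luminal, 16 mesenchymal, 23 proliferation and 29 neuroendocrine genes per library, by group on the horizontal axis, with group means and SD as bars. The mesenchymal mean lies at 12.34 to 12.96 in the exp libraries and 8.26 to 9.69 in the other abiraterone libraries, and the neuroendocrine mean lies at 5.28 and 10.86 in the outlier libraries.

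The 2 vehicle-treated NPp53 libraries labelled outlier were compared with the 3 other vehicle libraries, to describe mice set apart without abiraterone. The glycan enzyme B3gat1 (5.7 ± 1.15, adjusted p = 0.000427), the neuronal splicing factor Rbfox1 (4.9 ± 0.73, adjusted p = 1.87e-05) and the sodium channel Scn9a (4.83 ± 1.35, adjusted p = 0.00672) rose. Crmp1 (4.7 ± 0.87, adjusted p = 0.000188), a protein of growing axons, rose beside Ccdc147 (5.63 ± 0.91, adjusted p = 4.78e-05) and Mum1l1 (4.83 ± 0.97, adjusted p = 0.000442). The stromal marker Lrrc15 (5.45 ± 1.47, adjusted p = 0.0051) and the collagenase Mmp13 (4.7 ± 1.11, adjusted p = 0.00181) completed the rises. The antimicrobial lectin Reg3b (-8.56 ± 1.59, adjusted p = 0.000193), the mucin Muc5b (-8.55 ± 1.92, adjusted p = 0.00118) and the oxidase factor Duoxa2 (-8.21 ± 1.87, adjusted p = 0.00133) had the largest falls. Cxcl5 (-8.07 ± 1.26, adjusted p = 2.98e-05), Gsdmc2 (-8.05 ± 1.22, adjusted p = 2.29e-05) and Sftpd (-8.04 ± 1.35, adjusted p = 6.85e-05) followed. The protease Mmp7 (-8.02 ± 1.45, adjusted p = 0.000153) and Dmbt1 (-8.01 ± 1.58, adjusted p = 0.000362) fell with them. All 23 proliferation genes were higher, such as Ccnb1 (3.81 ± 0.4) and Top2a (3.58 ± 0.4). Of 12 luminal genes 8 fell (12 adjusted over the list alone), such as Spdef (-3.33 ± 0.73) and Cdh1 (-2.82 ± 0.84). Of 10 basal genes 9 fell, such as Col17a1 (-6.61 ± 0.69) and Krt5 (-7.35 ± 0.89). Luminal progenitor markers fell in 8 of 9 cases, such as Tacstd2 (-6.66 ± 0.94). Of 16 mesenchymal genes 6 rose, such as Cdh2 (4.56 ± 0.59) and Snai2 (1.82 ± 0.32). Fibroblast genes rose in 3 of 10 cases (median 1.29, adjusted p = 0.332). Of 27 neuroendocrine genes 6 rose (5 adjusted over the list alone), such as Ncam1 (2.16 ± 0.44), Uchl1 (4.07 ± 0.94) and Srrm4 (3.15 ± 0.81).

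Markers of neutrophils and B cells were lower in the outlier libraries, and the macrophage list was not called. All 7 neutrophil genes fell, such as Cxcr2 (-5.5 ± 0.96) and S100a8 (-5.89 ± 1.07). All 6 B and plasma cell genes fell, such as Ms4a1 (-4.49 ± 0.85). Macrophage genes rose in 1 of 10 cases and fell in 2 (median 0.36, adjusted p = 0.805), with list means of 11.48 and 9.71 in outlier replicates 1 and 2 and 10.44 to 10.94 in the other vehicle libraries. T cell genes fell in 6 of 9 cases, but the list was not called (median -1.8, adjusted p = 0.0501). Interferon response genes fell in 8 of 16 cases (9 adjusted over the list alone), such as Oas1a (-1.8 ± 0.41). Epidermal genes fell in 6 of 11 cases. Proliferation (median 2.95, adjusted p = 2.51e-16), mesenchymal (median 1.46, adjusted p = 0.00742) and neuroendocrine (median 1.83, adjusted p = 0.0164) genes were higher as lists, with adjusted p = 0.372 or higher with an estimated correlation. Luminal (median -2.45, adjusted p = 0.00183), basal (median -5.45, adjusted p = 5.09e-07), luminal progenitor (median -3.97, adjusted p = 0.000769), neutrophil (median -5.09, adjusted p = 0.001), B and plasma cell (median -3.84, adjusted p = 0.00183), interferon response (median -1.77, adjusted p = 0.0113) and epidermal (median -2.26, adjusted p = 0.0113) genes were lower as lists, with adjusted p = 0.359 or higher with an estimated correlation. Where list medians depended on 1 library, they were -1.07 for luminal and 0.22 for mesenchymal genes without outlier replicate 1, and -1.58 for neuroendocrine genes without outlier replicate 2. Vim stood at 15.38 in outlier replicate 1 and 12.57 in replicate 2. Of 27 androgen response genes 8 fell, such as Steap4 (-4.27 ± 0.66) and Ar (-2.89 ± 0.45), and 4 rose (median -0.5, adjusted p = 0.168). Cholesterol synthesis genes rose in 7 of 15 cases, such as Sqle (1.65 ± 0.36), and fell in 2 (median 0.57, adjusted p = 0.14). Trp53 fell by 1.04 ± 0.21 (adjusted p = 0.000455). In all 6827 of 16634 genes were called by limma (3366 higher, 3461 lower, n = 2 and 3). Of these, 2205 higher and 2384 lower genes were called in that direction in the exp comparison too, where independence gives 833.7 and 895.7. Only 46 and 59 were called in opposite directions (r = 0.75 across genes), from separate libraries but 1 shared fit. The count was 2734 in a fit of these groups alone and 1181 with quality weights, where 6 of 16 named genes were called. Quantile normalization gave 3728 higher and 3278 lower, and the fit without outlier replicate 1 gave 4067 and 3653. Without each single library 14 of the 16 were called, all but Lrrc15 and Scn9a.

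Exp and outlier libraries were compared with each other for differences between the sets, which also differ in treatment. Grem1 was higher in exp by 6.26 ± 0.64 (adjusted p = 2.42e-05), with the imprinted RNA H19 (6.36 ± 1.23, adjusted p = 0.00266). The prostaglandin synthase Ptgs2 (5.21 ± 1.54, adjusted p = 0.0292) and the growth factor Ereg (4.99 ± 0.9, adjusted p = 0.00169) were higher too. Adipsin Cfd (-5.68 ± 1.87, adjusted p = 0.0475), the LDL receptor regulator Pcsk9 (-3.99 ± 0.72, adjusted p = 0.00166) and Rbfox1 (-3.4 ± 0.73, adjusted p = 0.0053) and Glb1l2 (-3.24 ± 1.07, adjusted p = 0.0472) were lower. Of 16 mesenchymal genes 3 were higher in exp, Twist2 (3.2 ± 0.71), Itga5 (2.02 ± 0.58) and Vim (1.83 ± 0.54). Fibroblast genes were higher in 3 of 10 cases, such as Thy1 (2.6 ± 0.55). Of 15 cholesterol synthesis genes 8 were lower, such as Srebf2 (-1.09 ± 0.22). Neutrophil genes were higher in 3 of 7 cases and in 6 adjusted over the list alone, such as S100a8 (4.11 ± 1.07). Senescence and secretory factors were higher in 4 of 14 cases, such as Igfbp3 (2.15 ± 0.41) and Mmp3 (4.48 ± 1.01). Neuroendocrine genes had 0 of 27 called. Mesenchymal (median 1.35, adjusted p = 0.00236), fibroblast (median 1.3, adjusted p = 0.00394), neutrophil (median 3.41, adjusted p = 0.000797), senescence and secretory (median 1.64, adjusted p = 0.00123), endothelium (median 1.26, adjusted p = 0.00236), macrophage (median 0.59, adjusted p = 0.0137), glucocorticoid response (median 0.44, adjusted p = 0.02) and interferon response (median 0.99, adjusted p = 0.0125) genes were higher as lists, with adjusted p = 0.697 or higher with an estimated correlation. Cholesterol synthesis (median -0.81, adjusted p = 0.000797), neuroendocrine (median -1.44, adjusted p = 0.03) and proliferation (median -0.81, adjusted p = 0.00185) genes were lower as lists, with adjusted p = 0.697 or higher with an estimated correlation. Some list medians depended on 1 library and were 1.82 for neuroendocrine, 0.21 for mesenchymal, 0.74 for fibroblast, -0.39 for macrophage, -0.27 for proliferation and -0.49 for cholesterol synthesis genes without outlier replicate 2, and 0.78 for endothelium genes without exp replicate 1. In all 2187 of 16634 genes were called by limma (1123 higher, 1064 lower, n = 3 and 2). The count was 0 with quality weights (583 unadjusted), which ran from 0.105 to 0.263 in these libraries, and 0 in a fit of the 5 libraries alone (796 unadjusted). Quantile normalization gave 1043 higher and 1083 lower, and the fit without exp replicate 2 gave 1093 and 1337. The count was 6620 (2997 higher, 3623 lower) and 925 without outlier replicate 1 and 2 and 1264 and 3550 without exp replicate 1 and 3, and Grem1, H19 and Pcsk9 were the 3 of 8 named genes called without each single library.

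**Figure D4:**
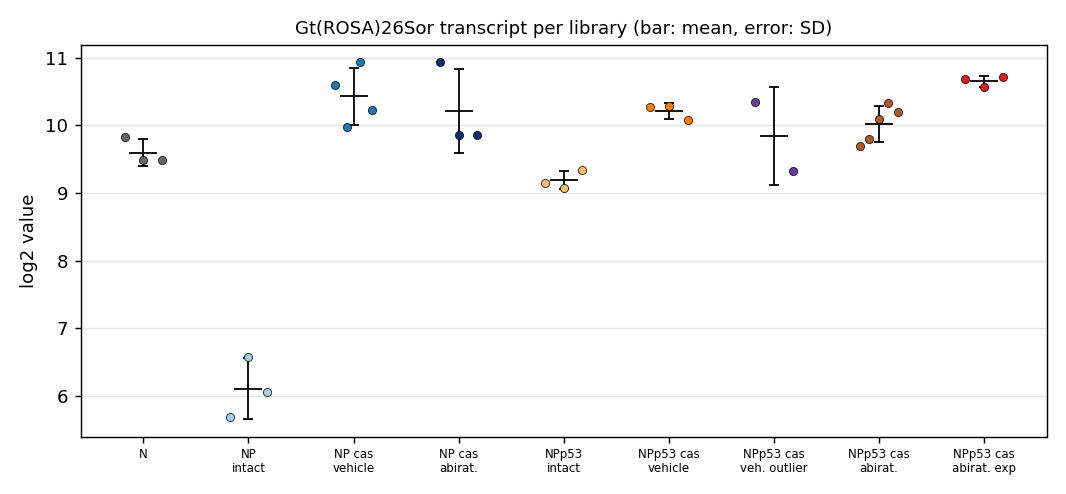
Log2 value of the Gt(ROSA)26Sor transcript per library, by group on the horizontal axis, with group means and SD as bars. The 3 intact NP libraries lie at 5.69 to 6.58 and the libraries of the other groups at 9.08 to 10.93.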

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

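All tests of explanations here were chosen after the results were seen, except the splits of the samples and the test without exp replicate 3. Single libraries far from their group were searched for in groups of 4 or 5 among 121 levels, and 7 were found where chance gives 6.1, about 1 in 20. Castrated NP vehicle replicate 4 had a skeletal muscle list mean of 5.63 (others 3.27 to 3.59), a B and plasma cell list mean of 6.85 (others 8 to 8.23) and an Svs5 level of 6.21 (others 2.86 to 3.32). In castrated NP vehicle replicate 3, Acp1 stood at 8.11 (others 8.96 to 9.08). NPp53 abiraterone replicate 5 had an interferon response list mean of 11.78 (others 9.98 to 10.29), Gsdmc2 at 12.97 (others 13.68 to 13.9) and Gsdmc3 at 12.66 (others 13.57 to 13.87).

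The castration interaction was called in 128 genes, some of which also differed between intact tumours. The named ones were Fam115e (difference 6.53), Spink11 (4.89), Fam55c (3.07), Gata2 (2.2), Acp1 (-5.53), Apol9b (-4.47), Ifit3 (-4.39) and Apol9a (-4.22), each in log2. Of 100 drawn splits of the libraries, only the real one gave as many (highest other 11). That argues against chance for the count, not for each call. The splits argue against chance for the counts of castration in NP (704 genes, 1 of 35 splits, highest other 114) and of castrated NPp53 against NP (42, 1 of 35, highest other 3). For exp against the other abiraterone libraries the splits decide nothing (8425, 1 of 56, highest other 3128), because the exp label can have followed from the outcome and the real split would then be the largest by selection. The splits were too few for NP against N (6261 genes, 1 of 10 splits, highest other 5), for NPp53 against NP intact (311, 1 of 10, highest other 5) and for castration in NPp53 (773, 1 of 10, highest other 1). For abiraterone they decide nothing either, since 0 genes were called and every split gives at least 0: 35 of 35 in NP (highest other 6), 100 of 100 drawn in NPp53 (highest other 3137) and 100 of 100 for the difference between genotypes (highest other 127). The split with 3137 genes placed the 3 exp libraries, outlier replicate 1 and another vehicle library in 1 arm and points to a structure along these labels.

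In the exp libraries mesenchymal genes were higher (16 of 16) and luminal genes lower (12 of 12). The fibroblast median exceeded the smooth muscle median by 4.18 log2 (95% interval 1.99 to 5.63 over 10000 resamples of genes, not mice). Schwann cell genes had a median of -1.65 and endothelium genes 1.4 (0.54 to 1.53). The gap argues against more stroma of unchanged mix, but not fibroblast-rich stroma. Low depth of exp replicate 3 is argued against by 16 mesenchymal genes called without it, among 7666. Abiraterone as sole cause stays open: 2205 genes rose in vehicle outliers too, but the mesenchymal median was 0.22 without replicate 1. Cells that escaped recombination as the source cannot be told apart from tumour cells that changed, because Trp53 differed by -0.22 (95% interval -0.57 to 0.13), and a change of state in tumour cells may account for the pattern as an untested hypothesis.

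Seminal vesicle transcripts varied within intact groups by up to 10.1 log2 in their list mean, against 3.78 for prostate secretory genes. Differing androgen activity would move the lists together, but the slope of the secretory on the seminal vesicle mean within groups was -0.11 (95% interval -0.289 to 0.07) over 9 intact libraries, which argues against it. Pearson's r was -0.35 (exact permutation p = 0.407, two-sided, 216 permutations within groups) and Spearman's rho -0.12 (exact permutation p = 0.852), with r = -0.34 without the 2 farthest libraries, in a family of 1 relation. Tissue carried over at dissection may account for the variation. Of the within-group variance of the 9 genes, 95% lay on 1 component. That does not tell it from androgen activity, which could also move these genes together, and no other biological explanation was tested.

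Gt(ROSA)26Sor lay lower in intact NP (6.11 ± 0.45, SD, n = 3) than in N (9.6 ± 0.2), by -3.49 ± 0.29 in the fit. Lower depth is argued against by a mean of 22.5 M reads in intact NP against 21.06 in N, and a change of the whole region by its neighbours Thumpd3 (-0.55 ± 0.14) and Setd5 (-0.07 ± 0.12), both far smaller. A Rosa26 allele that the labels of the intact NP mice do not give could account for it only if it lowers the transcript. The labelled reporter did not: among castrated NP mice the level was higher by 0.85 in 3 EYFP/EYFP than in 4 EYFP/+ mice (exact permutation p = 0.0286, two-sided, the smallest that 35 arrangements can give), which says nothing about another allele. This explanation cannot be told apart from a real loss of expression, because the labels of intact mice name no allele, and no biological explanation was tested.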

How the results depend on the processing

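The seminal vesicle covariate, the fit without the exp and outlier libraries and list medians without 1 library were tests chosen after the results were seen, and the others were planned. Of 128 named gene results, 54 were called under every alternative run. Over these named results and their alternatives 1493 values kept their call, 350 lost it and 5 changed sign. Array quality weights gave 11596 genes for NP against N, 9825 for NPp53 against NP, 8536 for castration in NP, 6018 for castration in NPp53, 3665 for castrated NPp53 against NP, 1031 for abiraterone in NP, 5560 for exp, 1181 for outlier, 0 for exp against outlier and 6356 for the castration interaction. These weights ran from 0.105 to 31.819, the latter for NP intact replicate 3, their estimation stopped before convergence, and 2 of 35 splits gave as many genes as abiraterone in NP (highest other 1777). A fit of only the groups compared gave 951 genes for NPp53 against NP, 4347 for castration in NPp53, 1334 for castrated NPp53 against NP, 2734 for outlier, 0 for exp against outlier and 1519 for the interaction. The fit without the exp and outlier libraries gave 1358, 2134, 2703, 858 and 824 genes for NPp53 against NP, castration in NP, castration in NPp53, castrated NPp53 against NP and the interaction, with fewer widely spread libraries in the estimate of spread by construction. With the seminal vesicle covariate, which varies mainly with the contrast itself in castration, counts were 72 for NPp53 against NP, 72 for castration in NP and 5 for the interaction, and Svs1 (0.49), Svs6 (1.41), Svs3b (1.24), Svs3a (1.52) and Sva (2.11) changed sign after castration in NP, since the covariate is built from such genes. All 5 vehicle libraries as 1 group gave 1886 genes for castration in NPp53 and 1035 for castrated NPp53 against NP. The interaction had 52 genes with no filter and 77 after quantile normalization. The 122 list calls became 1 with the estimated correlation, and without 1 library 6 of their medians turned and 41 shrank by over 1.5 times. Unless stated, the cause was not tested.

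Leaving out 1 library gave 4838 to 6038 genes for NP against N, 65 to 185 for NPp53 against NP, 185 to 681 for castration in NP, 241 to 405 for castration in NPp53, 16 to 35 for castrated NPp53 against NP, 0 to 0 for each abiraterone comparison and the abiraterone interaction, 7290 to 8326 for exp, 5720 to 7720 for outlier, 925 to 6620 for exp against outlier and 4 to 131 for the castration interaction. Where 1 outlier library remained, it was assumed to vary like the other groups. The other alternatives moved no count by over 1.5 times, and the abiraterone counts in NPp53 stayed at 0, with 782 unadjusted when the exp and outlier libraries were left out. Other pseudocounts and DESeq2 were not run, since the file holds logs and no counts. Depth was estimated, and 8.54 M reads in exp replicate 3 limits its low values.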

Other observations

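Neuroendocrine genes differed between single libraries of the sets apart. Outlier replicate 2 had a list mean of 10.86, with the neuronal fate factor Ascl1 at 13.83, chromogranin Chga at 12.48, synaptophysin Syp at 11.87 and the transcription factor Foxa2 at 11.75, while outlier replicate 1 had a list mean of 5.28, with Ascl1 at 4.81 and Chga at 5.73. Among exp libraries the list mean was 4.58, 6.52 and 8.55 in replicates 1, 2 and 3, with Ascl1 at 3.25 in replicate 1 and 12.66 in replicate 3. NPp53 abiraterone replicate 1, not set apart by the labels, had a list mean of 7.35 and Ascl1 at 10.35, and the remaining libraries of the series had list means of 3.97 to 6.61. Mesenchymal list means were 12.36 and 10.33 in outlier replicates 1 and 2, so the outlier library with the higher neuroendocrine mean had the lower mesenchymal mean. Luminal list means were 8.56 and 11.56 in the outlier libraries and 6.65, 11.02 and 9.2 in the exp libraries.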
